A study of Sus scrofa with 73 samples.

How the data were processed

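Hypothalamus RNA of 73 pigs, each aged 22 days, was sequenced. The labels give 3 factors that make 8 groups: maternal immune activation (MIA, an immune challenge of the mother) or control, female or male, and nursed or weaned. Groups held 7 to 11 pigs, with 40 control and 33 MIA pigs, 36 female and 37 male pigs, and 35 nursed and 38 weaned pigs. The agent used for the challenge is not given in the sources used here. Total RNA was isolated with TRIzol and a column kit, and stranded mRNA libraries were sequenced over 101 cycles in an early batch of 4 lanes and a later batch of 5 lanes, per the labels' protocols. The protocols speak of reads from one end of each fragment and the series' design text of paired ends. The lane, litter and sow of each pig are not given in the sources used here, so p-values treat the pigs as independent.

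The authors deposited 1 table of CPM values (a gene's reads per mega reads, M, assigned in the library) with a line for each gene symbol and a column for each library. The program kallisto 0.43, which assigns reads to transcripts, is named in the submitters' processing notes. The genome build and transcript set are not given in the sources used here. The unit was read from the values: column sums lay between 0.912 and 0.933 M, and in each library the smallest steps between values gave the number of reads that make 1 CPM. This gave 30.4 to 72.2 M assigned reads per library, with a median of 45.4 M. Between 64.4 and 76.2% of a library's nonzero values were whole reads to within 0.01 reads. The others were fractions, as arise when a read is shared among transcripts, so values of genes with near-identical copies, such as the SLA, OAS and GIMAP families, are uncertain. The table is in alphabetical order and ends within the letter T: of its 25187 lines, 25186 were complete, TRIM21 was the last complete symbol and TRIM23 the incomplete one, and symbols after it were not analysed here. Of the symbols, 25158 matched RefSeq names for the pig, which were used for names only.

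CPM values were scaled by an own implementation of unweighted trimmed means of M-values (trims of 30% for ratios and 5% for levels) and are called scaled CPM. Genes with at least 0.22 scaled CPM, which is 10 reads at the median depth, in at least 7 libraries were kept: 19424 genes, of which 5461 carry only a LOC number. Values were tested as log2 of scaled CPM plus 0.5, which shrinks the fold change of genes at low levels. limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options) fitted a mean for each of the 8 groups. The main effects average the 4 differences within the strata of the other factors, and interactions, MIA effects in nursed and in weaned pigs, and weaning effects in control and in MIA pigs are contrasts of the same fit. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and the threshold was an adjusted p of 0.05. Levels are given as mean scaled CPM with the SD, and differences as log2 fold changes with the standard error from limma.

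The comparisons, the rule for the genes named, 33 gene lists and some of the alternatives were written before the data were examined. They assumed estimated read counts and tests for counts; since the table holds CPM, limma on log2 values took their place. The rule took, among genes with a symbol other than a LOC number past the threshold and with the same sign in all strata, at most the 10 higher and 10 lower genes with the smallest p for MIA and weaning, and 5 and 5 for sex and for effects within 1 level of another factor. It added up to 15 further list members past the threshold and 16 hypothalamic neuropeptide genes, and where none passed, the 3 genes with the smallest p. Lists with at least 5 tested members, 32 of the 33, were tested with camera of limma on the same log2 values, at a preset correlation between genes of 0.01. Each test was repeated with the correlation estimated from the data, and with fry, which asks whether the genes of a list move one way.

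The first principal component held 77.4% of the variance and parted the libraries into 2 sets, called library set 1 (48 libraries) and library set 2 (25 libraries). Each fit was therefore repeated with the set as a term, called the set term, and within each set. Alternatives also covered other scalings, pseudocounts of 0.1 and 2 CPM, no filter on low values, sample weights, 2 tissue scores (mean standardised levels of hypothalamic regional transcription factors and of myelin genes), the replicate number as a block, additive models, single strata, and leaving out each library in turn or 2 libraries whose sex genes went against the label. Those with the set term, single library sets, the scores, the pseudocounts, the deposited CPM without scaling, and libraries left out were chosen after seeing the data. The splits of the samples and permutation tests used fixed seeds, and no library was left out of the comparisons.

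The fits were tested on simulated data, made from the same libraries with group effects removed and pigs shuffled within library sets, in 5 runs with 200 changed genes each. For MIA, the fit of the 8 groups recovered 15.2% of genes changed 1.2-fold, 38.8% at 1.5-fold, 70.8% at 2-fold and 82.8% at 3-fold, and the fit with the set term 36.8, 78, 92.4 and 98.8%. For weaning, the shares were 10, 38.4, 67.2 and 82.4%, and with the set term 37.6, 79.2, 93.2 and 98%. False calls were 0.575% of calls for MIA and 0% for weaning, and 4.49 and 2.28% with the set term. Since pigs were shuffled singly, these shares do not cover pigs that share a litter, or the wider spread among MIA pigs described below. With the preset correlation, camera called 46 of 155 unchanged lists for MIA and 54 of 155 for weaning, while it called 0 of 155 for each with an estimated correlation. Calls of lists that held only with the preset correlation are therefore given with their adjusted p at an estimated correlation.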

Results

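The series addresses how an immune challenge of the mother, sex and weaning bear on the hypothalamus of 22-day-old pigs. All 73 libraries entered the comparisons, at 30.4 to 72.2 M assigned reads each. The widest difference among them was between the 2 library sets. Set 2 held 25 libraries, 2 to 5 in each of the 8 groups (Fisher's exact test of set against group, p = 0.98), and 17638 of the 19424 genes tested differed between the sets. Replicates 1 and 2 of each group were all in set 1, and replicates 9 to 11 all in set 2. The depth of all 48 libraries of set 1 lay within the depth range of set 2.

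**Figure D1:**
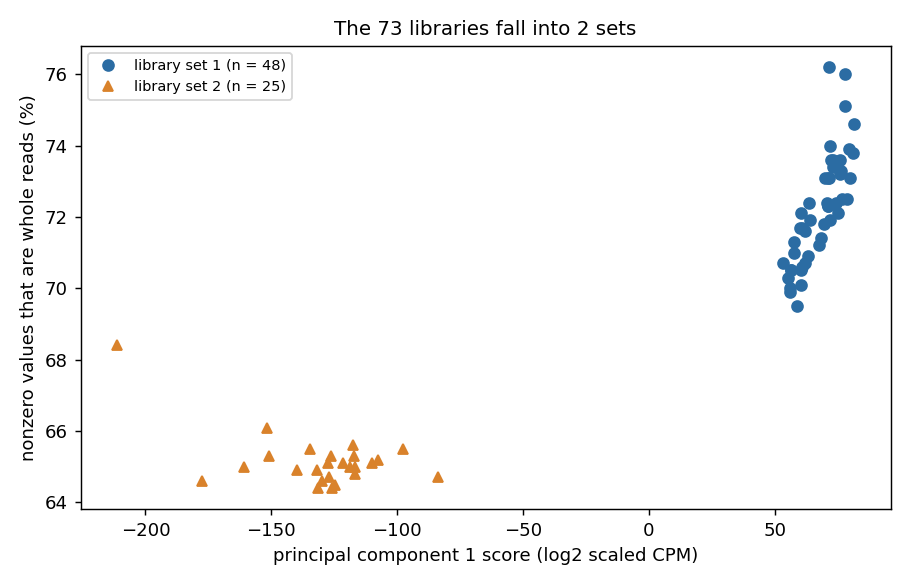
Each point is a library, with its score on the first principal component of log2 scaled CPM (no unit) on the x axis and the percentage of its nonzero values that are whole reads on the y axis. Set 1 (circles, n = 48) held 69.5 to 76.2% whole values and set 2 (triangles, n = 25) 64.4 to 68.4%.

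The lists of antigen presentation and interferon response genes were higher in 33 MIA than in 40 control pigs, with 8 of 27 and 6 of 37 tested members past the threshold. Of 17 blood cell markers 3 passed, and that list did not pass with the set term and an estimated correlation (adjusted p = 0.105). SLA-DRA, a chain of the class II molecule that presents antigen to T cells, averaged 14.2 ± 19.8 scaled CPM (SD, n = 33) in MIA and 1.62 ± 2.2 (n = 40) in control pigs. Its log2 fold change was 1.86 ± 0.35 (SE, adjusted p = 0.00342). CD74, the invariant chain that guides class II molecules through the cell, averaged 31.7 ± 33.6 against 7.68 ± 6.94 scaled CPM (1.56 ± 0.33, adjusted p = 0.0108). OAS1, an oligoadenylate synthase that senses double-stranded RNA, averaged 15.9 ± 15.5 against 5.9 ± 4.33 scaled CPM (1.24 ± 0.23, adjusted p = 0.00306). GIMAP7, a GTPase of lymphocytes, had the smallest p among genes with a symbol other than a LOC number (4.27 ± 1.06 against 2.93 ± 0.751 scaled CPM, 0.47 ± 0.08, adjusted p = 0.000649).

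In all, 54 genes differed between MIA and control pigs in limma, 50 higher and 4 lower, and 860 had an unadjusted p under 0.05. In the fit with the set term the count was 185 (161 higher, 24 lower), and it included all 54. The balance was less one-sided with the set term and tissue scores (476 genes, 351 higher and 125 lower) and with sample weights (1515 genes, 918 higher and 597 lower). Within set 1 and within set 2, 54 of the 54 genes kept their direction, with median absolute log2 fold changes of 0.67 and 0.45 against 0.62 over all pigs. Of them, 28 passed in limma within set 1 and 0 within the 25 libraries of set 2, where GVIN1, named after its value was seen, was the 1 gene that passed and 976 had an unadjusted p under 0.05. Without MIA_Male_Nursed replicate 1 the count was 85. The same direction in all 4 strata of sex and weaning was a condition for naming the genes with the smallest p; the list members named without that condition also rose in 4 of 4.

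**Figure D2:**
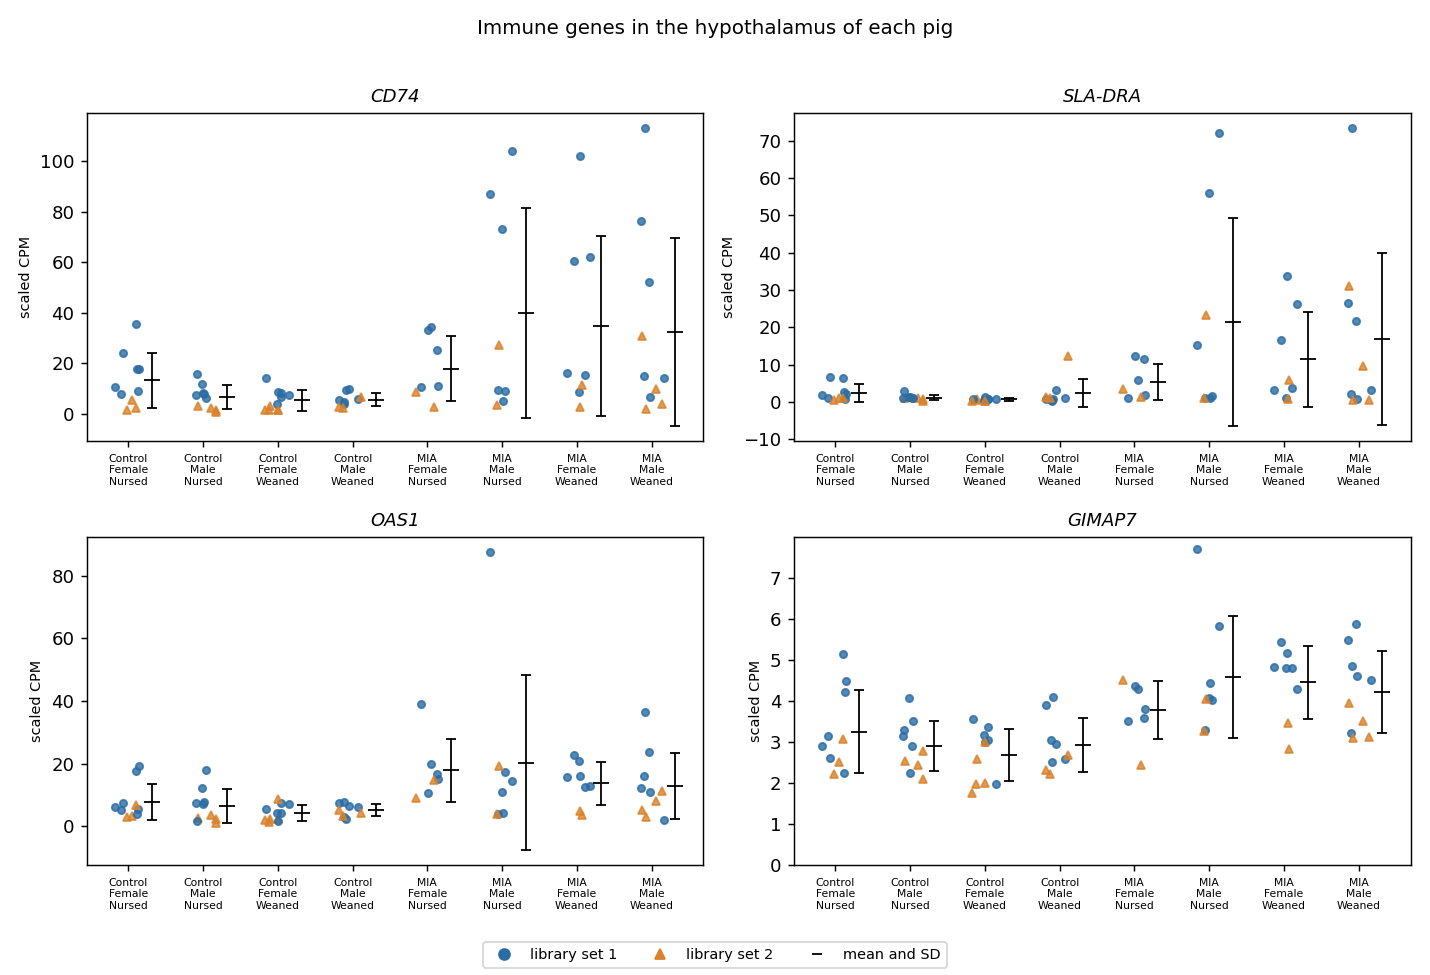
Scaled CPM of CD74, SLA-DRA, OAS1 and GIMAP7 (y axes) in each pig (points) of the 8 groups (x axes), with the mean and SD of each group (7 to 11 pigs). SLA-DRA averaged 1.62 scaled CPM over control and 14.2 over MIA pigs, with an SD of 19.8 among MIA pigs.

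Of the 27 tested genes of antigen presentation, 8 rose in MIA pigs, 0 fell and 19 did not pass the test. Adjusted over the list alone, 20 rose. The 8 took in the class II chains SLA-DQA1 (1.61 ± 0.31, 7.8 against 0.996 scaled CPM, adjusted p = 0.00485), SLA-DRB1 (1.25 ± 0.26) and SLA-DQB1 (1.43 ± 0.3). The class I chain SLA-3 rose as well (0.99 ± 0.18, 87.4 ± 56.4 against 38.5 ± 16.4 scaled CPM, adjusted p = 0.00306). PSMB9, a subunit of the immunoproteasome, rose by 0.83 ± 0.19, and CTSS, a protease that processes the invariant chain, by 0.54 ± 0.12. The list as a whole was higher (camera, adjusted p = 3.88e-43 with the preset and adjusted p = 0.00156 with an estimated correlation, 0.00192 with the set term as well, 0.0492 within set 1 and 0.152 within set 2). Adding the set term, 19 members rose, 24 when adjusted over the list alone.

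Of 37 tested genes of the interferon response, 6 rose, 0 fell and 31 did not pass. Adjusted over the list alone, 31 rose, and with the set term 19 rose, 34 over the list alone. Besides OAS1 these were OAS2 (0.78 ± 0.15, 58.5 ± 40.9 against 29.8 ± 11.1 scaled CPM) and RSAD2, an antiviral enzyme induced by interferon (1.37 ± 0.33, 16.2 ± 28.9 against 4.17 ± 5.16). The others were the helicase DDX60 (1.08 ± 0.26), the ubiquitin ligase HERC6 (0.71 ± 0.16) and IRF9, a transcription factor of interferon signalling (0.5 ± 0.11). Their adjusted p lay between 0.00306 for OAS1 and 0.0358 for RSAD2. The list was higher as a whole (adjusted p = 2.87e-48 with the preset and adjusted p = 0.00156 with an estimated correlation, 0.0146 with the set term as well). It did not pass within set 1 (0.146) or set 2 (0.152) at an estimated correlation.

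Of 17 tested blood cell markers, 3 rose, each of lymphocytes, or 4 adjusted over the list alone. They were CD3D and CD3E, parts of the T cell receptor complex (0.41 ± 0.09 and 0.62 ± 0.14), and GZMA, a protease of killer cells (0.58 ± 0.13). Their levels were low, at 0.258, 0.553 and 0.468 scaled CPM in MIA and 0.0266, 0.0535 and 0.0367 in control pigs. The control means lay below the floor of 0.22 scaled CPM, where the 0.5 added before log2 shrinks the fold change. CD3E did not pass at a pseudocount of 2 CPM (log2 fold change 0.25, adjusted p = 0.0527). The list passed with both correlations (1.57e-08 and adjusted p = 0.0363 with an estimated correlation), and not with the set term and an estimated correlation together (0.105). Outside the lists, GNLY, a protein that killer lymphocytes use against target cells, rose from 0.18 to 1.31 scaled CPM (1 ± 0.18). So did CCR2, a chemokine receptor of monocytes (0.5 ± 0.09), and SELP, an adhesion molecule of platelets and vessel walls (0.75 ± 0.14), each with an adjusted p of 0.00306. The log2 fold changes of GNLY and CCR2 were larger at a pseudocount of 0.1 CPM and smaller at 2 CPM, and both genes passed with each. CCL5, a chemokine, rose as 1 of 26 tested inflammatory genes (0.92 ± 0.22), and did not pass at a pseudocount of 0.1 CPM (1.38, adjusted p = 0.067). Adjusted over the list alone 3 rose and 1 fell, and the list passed at 3.54e-07 with the preset, but adjusted p = 0.0811 with an estimated correlation. DHRS9, a dehydrogenase that acts on retinol, rose by 0.55 ± 0.11 (adjusted p = 0.0094).

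Genes that fell in MIA pigs were SSPN, a membrane protein of the dystrophin complex (43.7 ± 7.3 against 51.4 ± 6.1 scaled CPM, −0.24 ± 0.05, adjusted p = 0.0173) and FPGT, an enzyme of fucose metabolism (−0.35 ± 0.08). HAO2, an oxidase of hydroxy acids, fell too (−0.22 ± 0.05), as did LOC102159645, named here after its value was seen. With CPM as deposited, SSPN (adjusted p = 0.077), FPGT (0.129) and HAO2 (0.134) did not pass. SSPN did not pass with sample weights either, at a log2 fold change of −0.08 (adjusted p = 0.296), nor did HAO2 with RLE size factors (adjusted p = 0.0574). Markers of microglia, the resident macrophages of the brain, showed 1 of 21 higher, which was CTSS; the list passed at 0.000545 with the preset, but adjusted p = 0.484 with an estimated correlation. The preset correlation also gave calls with 0 members past the test in limma over all genes for immediate early genes (0.000103), vascular and meningeal markers (0.000109), regional transcription factors of the hypothalamus (0.00225), pituitary markers (0.00341), cell proliferation (0.00548) and monoamine systems (0.0435), all higher. Ependymal and tanycyte markers (0.016) and GABA and glutamate transmission (0.0183) were called lower in the same way. For these 8 lists the adjusted p = 0.484 with an estimated correlation. For ribosomal proteins (0.000163) and oxidative phosphorylation (0.0112), both higher, it was adjusted p = 0.731 with an estimated correlation. The other 17 lists, with appetite, stress axis, glucocorticoid-induced, clock, cholesterol and myelin genes among them, had adjusted p between 0.189 and 0.956 with the preset correlation.

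Neuropeptide genes of the hypothalamus varied widely among pigs, and 0 of 16 passed the test in limma for MIA or for weaning, with 0 under an unadjusted p of 0.05. For MIA the log2 fold changes included 0.87 ± 0.59 for PMCH, the precursor of melanin-concentrating hormone (p = 0.144), and 0.29 ± 0.52 for POMC, the precursor of melanocortins. AGRP and NPY, which drive feeding, gave 0.41 ± 0.48 and 0.23 ± 0.45. For weaning they included 0.38 ± 0.23 for CRH, the releasing hormone of the stress axis (p = 0.108), −0.53 ± 0.52 for POMC and −0.33 ± 0.48 for AGRP. HCRT, the orexin precursor, averaged 96.6 ± 111 scaled CPM in MIA and 95.5 ± 121 in control pigs. Adjusted p were at least 0.855 for MIA and 0.946 for weaning. The direction of several of these genes differed between alternatives, without a call. With sample weights in limma TRH, the precursor of thyrotropin-releasing hormone, passed for MIA (−1.19, adjusted p = 0.0222, against −0.01 without weights), and CRH for weaning (0.66, adjusted p = 0.041).

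Weaned pigs had more RNA of PDK4, FKBP5 and the list of glucocorticoid-induced genes, and less of the list of cell proliferation genes, than nursed pigs. PDK4, a kinase that restrains the oxidation of glucose, averaged 142 ± 38.2 scaled CPM in 38 weaned and 79.4 ± 25.6 in 35 nursed pigs, a log2 fold change of 0.88 ± 0.1 (SE, adjusted p = 1.68e-08). SLC14A1, a urea transporter, averaged 199.8 ± 53.1 against 123 ± 35.2 scaled CPM (0.7 ± 0.1, adjusted p = 1.69e-05). FKBP5, a chaperone of the glucocorticoid receptor, averaged 78 ± 29.4 against 51.3 ± 16.1 scaled CPM (0.57 ± 0.12, adjusted p = 0.00888). POLE, the catalytic subunit of a replicative DNA polymerase, averaged 1.53 ± 0.467 against 2.46 ± 0.808 scaled CPM (−0.53 ± 0.09, adjusted p = 0.000511).

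In all, 35 genes differed with weaning in limma, 22 higher and 13 lower, and 655 had an unadjusted p under 0.05. With CPM as deposited, without scaling, another list of 35 genes passed, 17 higher and 18 lower. It held 29 of the 35 genes above, all of which kept their direction. FKBP5 (adjusted p = 0.0877), CPT1A (0.289) and MYLIP (0.23) were not among them. In the fit with the set term 171 genes passed (72 higher, 99 lower), all 35 among them. It was 745 with the tissue scores as well (266 higher, 479 lower), and 611 with sample weights (236 higher, 375 lower). Within each set, 35 of the 35 kept their direction, with median absolute log2 fold changes of 0.47 in set 1, 0.36 in set 2 and 0.44 over all pigs. In limma 30 of them passed within set 1 and 0 genes within set 2, where 607 genes had an unadjusted p under 0.05. Without the 2 libraries whose sex genes went against the label, 57 genes passed (30 higher, 27 lower). Of the list members, which were named without the condition of 1 direction in all strata, NEU4 rose in 3 of 4 strata of MIA and sex and averaged 46.3 scaled CPM in nursed and 45.5 in weaned MIA females. The others went the same way in 4 of 4.

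**Figure D3:**
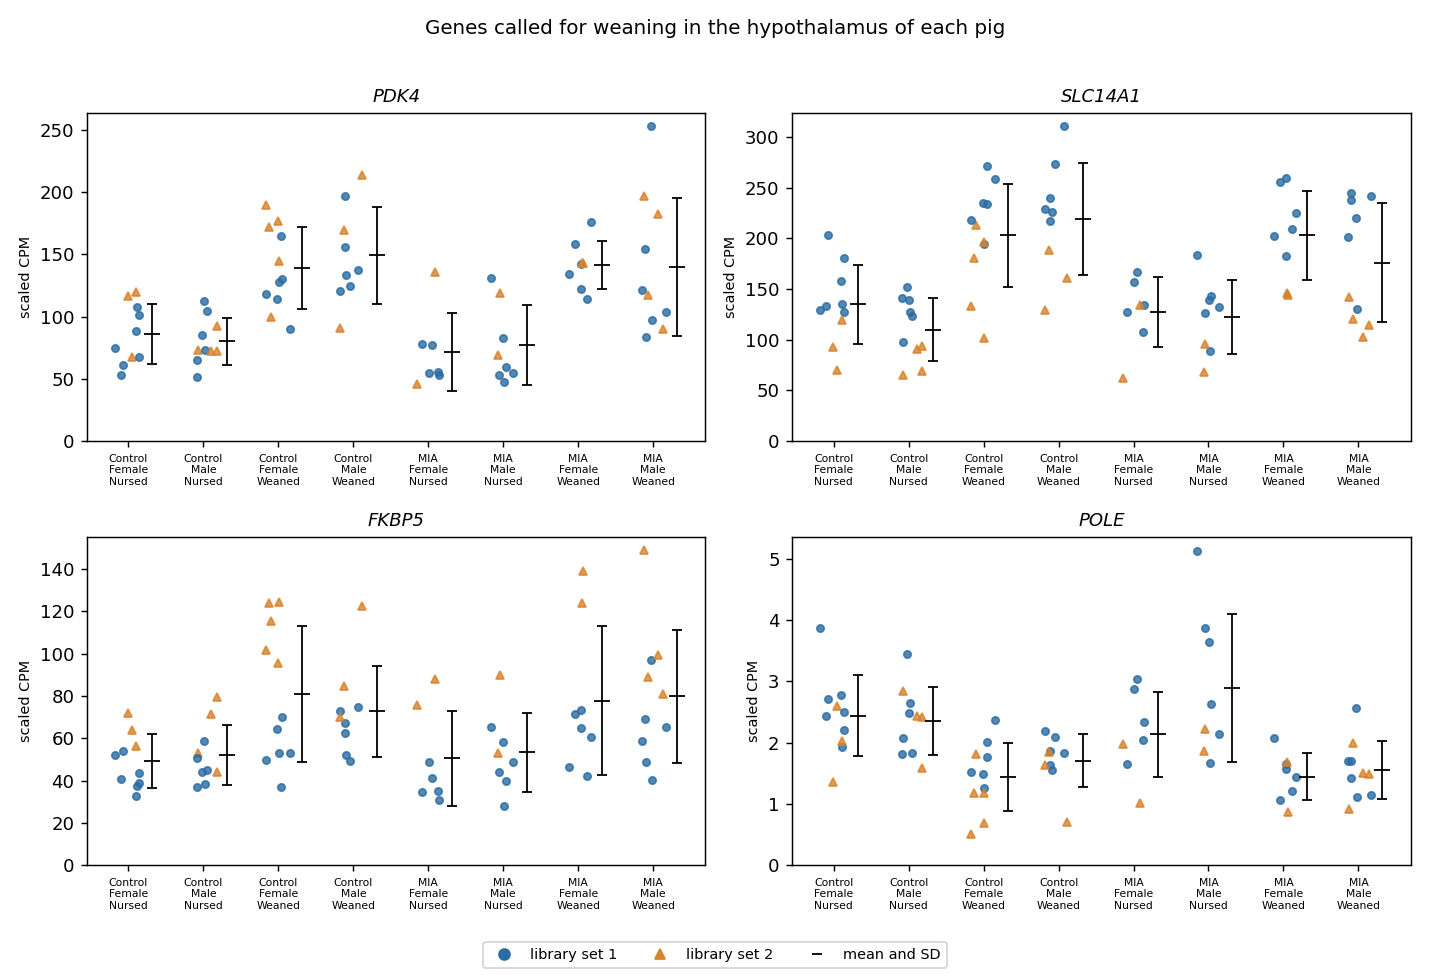
Scaled CPM of PDK4, SLC14A1, FKBP5 and POLE (y axes) in each pig (points) of the 8 groups (x axes), with the mean and SD of each group (7 to 11 pigs). PDK4 averaged 79.4 scaled CPM over nursed and 142 over weaned pigs, and POLE 2.46 and 1.53.

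Of 20 tested glucocorticoid-induced genes, 2 rose in weaned pigs (PDK4 and FKBP5), 0 fell and 18 did not pass; adjusted over the list alone, 9 rose. With the set term 5 rose, among them ANGPTL4, an inhibitor of lipoprotein lipase (0.62, adjusted p = 0.00169), ARRDC2 (0.5, 0.00224) and the metallothionein MT1A (0.39, 0.031), and 9 over the list alone. The list was higher (camera, 3.28e-11 with the preset and adjusted p = 0.0132 with an estimated correlation, 0.00206 with the set term as well, 0.0121 within set 1 and 0.387 within set 2). Of 22 tested genes of fatty acid use and ketone metabolism, 2 rose: PDK4, which is on both lists, and CPT1A, which admits fatty acids to mitochondria (92.2 against 77.8 scaled CPM, 0.25 ± 0.06, adjusted p = 0.0247). Adjusted over that list alone 3 rose, and the list passed at 0.000101 with the preset, but adjusted p = 0.0551 with an estimated correlation.

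Of 23 tested cell proliferation genes, 3 fell in weaned pigs, 0 rose and 20 did not pass; adjusted over the list alone, 14 fell. They were BUB1B, a kinase of the spindle checkpoint (−0.43 ± 0.1, adjusted p = 0.0212), and MCM3, a part of the replicative helicase (−0.33 ± 0.08, 0.0247). The third was RRM2, a subunit of ribonucleotide reductase (5.66 ± 1.84 against 8.93 ± 5.99 scaled CPM, −0.55 ± 0.12, 0.0247). With the set term 7 fell, 17 over the list alone. The list was lower with both correlations (5.99e-26 and adjusted p = 0.00126 with an estimated correlation, 0.0198 with the set term as well). It did not pass within set 1 (0.0568) or set 2 (0.634) at an estimated correlation. Outside the lists, DTL, an adaptor that marks replication proteins for breakdown (−0.43 ± 0.09, adjusted p = 0.00557), fell as well. Other genes that fell were the metalloprotease ADAMTS16 (−0.44 ± 0.09), the phosphodiesterase GDPD2 (−0.55 ± 0.11), STYK1 (−0.22 ± 0.05) and TBATA (−0.89 ± 0.19), with adjusted p between 0.00511 and 0.018. TBATA did not pass at a pseudocount of 0.1 CPM (−1.33, adjusted p = 0.0524) or within set 1 (adjusted p = 0.0508).

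Other genes that rose in weaned pigs were IRS2, which relays the signal of the insulin receptor (56.4 against 44.6 scaled CPM, 0.33 ± 0.05, adjusted p = 7.46e-05), TMEM100 (113 against 86.1, 0.41 ± 0.06) and MRO (12.1 against 8.13, 0.57 ± 0.08). So were the methyltransferase SETD7 (0.35 ± 0.06), the interleukin receptor IL17RB (0.53 ± 0.09) and MYLIP, a ligase that targets the receptor for low-density lipoprotein (0.24 ± 0.05). The cytochrome CYP4F55 (0.58 ± 0.12) and FIBIN (0.45 ± 0.09) rose as well. NEU4, a sialidase on the list of oligodendrocyte precursor markers, rose from 40.2 to 49.1 scaled CPM (0.28 ± 0.06, adjusted p = 0.0256), as 1 of 12 tested members, and that list did not pass (0.188). In the additive model NEU4 did not pass (0.29, adjusted p = 0.0506). Myelin genes were higher as a list of 22, with 0 members past the test in limma over all genes (0.00839 with the preset, but adjusted p = 0.717 with an estimated correlation). Ependymal and tanycyte markers were lower with the preset correlation alone (2.75e-06, but adjusted p = 0.118 with an estimated correlation). The same held for cholesterol synthesis and oxidative phosphorylation (both 0.00293), heat shock genes (0.00982) and pituitary markers (0.0273), each with adjusted p = 0.717 with an estimated correlation. Ribosomal proteins were also lower (0.00982, but adjusted p = 0.76 with an estimated correlation).

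Within control pigs, 9 genes rose with weaning and 0 fell in limma (618 with an unadjusted p under 0.05). Among them were PDK4 (0.79 ± 0.13, adjusted p = 0.00161), SLC14A1 (0.8 ± 0.14, 0.00161), MRO (0.63 ± 0.11), IRS2 (0.37 ± 0.07), CYP4F55 (0.8 ± 0.16) and NEU4 (0.41 ± 0.09). Within MIA pigs, PDK4 alone passed (0.96 ± 0.15, adjusted p = 0.000233). The difference between these 2 effects did not pass for PDK4 (0.17 ± 0.2, p = 0.403). Adding the set term, the counts were 110 in control and 19 in MIA pigs. Leaving out 1 library at a time in that fit, they ran from 47 to 226 and from 6 to 28, and sample weights gave 260 and 83. With CPM as deposited, IRS2 (adjusted p = 0.445), CYP4F55 (0.147) and NEU4 (0.0851) did not pass in control pigs, nor did NEU4 with the control pigs alone (adjusted p = 0.0905).

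The MIA effect within weaned pigs passed for GIMAP7 alone (0.55 ± 0.11, adjusted p = 0.0431), and within nursed pigs 0 genes passed in limma, with 422 at an unadjusted p under 0.05. Without the 2 libraries whose sex genes went against the label, GIMAP7 did not pass (adjusted p = 0.0652), nor with the weaned pigs alone (adjusted p = 0.106), and leaving out 1 library at a time gave 0 to 10 genes. With the set term 34 genes passed in weaned and 0 in nursed pigs, where 1462 then had an unadjusted p under 0.05. Leaving out 1 library at a time, the 34 became 1 to 70, and sample weights gave 643 genes in weaned and 110 in nursed pigs. Among nursed pigs the smallest p were those of OAS1 (1.24 ± 0.33, p = 0.000445), FAM72A (0.37 ± 0.1, p = 0.000696) and CCDC17 (0.86 ± 0.24, p = 0.000801), of which the last 2 passed with sample weights (adjusted p = 0.0221 and 0.0105). The difference between the effects in weaned and nursed pigs did not pass for GIMAP7 (0.17 ± 0.15, p = 0.282) or CD74 (0.67 ± 0.65, p = 0.309).

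For each interaction 0 genes passed in limma, without and with the set term. With sample weights in limma 3 passed for MIA by sex, among them RYR1 (adjusted p = 0.00919). The genes with an unadjusted p under 0.05 were 213 for MIA by weaning (2171 with the set term), 73 for MIA by sex (265), 370 for weaning by sex (1719) and 54 for the interaction of all 3 factors (262). The smallest p in the fit without weights or set term, none past the threshold, were ETV4 (−0.64 ± 0.2, p = 0.00198), GPR12 (0.68 ± 0.22, p = 0.00313) and ANKRD34C (0.7 ± 0.23, p = 0.00367) for MIA by weaning. For MIA by sex they were RYR1, a calcium release channel (1 ± 0.25, p = 0.00016), HPSE (−0.62 ± 0.17, p = 0.000765) and IL31RA (−0.52 ± 0.18, p = 0.00575). For weaning by sex they were NEU4 (0.49 ± 0.13, p = 0.000261), SPACA1 (−0.31 ± 0.1, p = 0.0022) and PHF10 (0.34 ± 0.11, p = 0.00265). For all 3 factors they were LHFPL1 (−1.01 ± 0.37, p = 0.00785), CES5A (0.82 ± 0.3) and BPIFC (−0.69 ± 0.27).

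Gene lists passed for interactions with the preset correlation alone: 11 of 32 for MIA by weaning, 7 for MIA by sex and 18 for weaning by sex. With an estimated correlation the counts were 0, 0 and 0 (smallest adjusted p 0.503, 0.864 and 0.0505). For weaning by sex, the change with weaning was lower in males than in females for appetite genes (median −0.52 on the log2 scale; 2.11e-10, but adjusted p = 0.0505 with an estimated correlation). It was higher in males for myelin genes (median 0.67; 2.99e-10, but adjusted p = 0.217 with an estimated correlation). The regional transcription factors of the hypothalamus went the way of the appetite genes (median −0.49; 1.87e-07, but adjusted p = 0.171 with an estimated correlation). For MIA by weaning, cell proliferation genes were lower (median −0.2; 1.94e-06, but adjusted p = 0.503 with an estimated correlation), and for MIA by sex, ribosomal proteins (median −0.2; 6.75e-09, but adjusted p = 0.876 with an estimated correlation).

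Between the sexes, 20 genes differed in limma, 16 higher and 4 lower in males (184 with an unadjusted p under 0.05; 27 with the set term). EIF1AY, a Y-linked translation factor gene, averaged 51.8 ± 13.8 scaled CPM in 37 male-labelled and 2.4 ± 14.4 in 36 female-labelled pigs (6.26 ± 0.28, adjusted p = 1.96e-29). Of 7 tested X-linked genes with a Y partner or a role in X inactivation, 2 were lower in males and 5 did not pass. EIF2S3, also a translation factor, averaged 73.2 ± 23.7 against 107 ± 21.8 scaled CPM (−0.55 ± 0.08, adjusted p = 6.37e-07). KDM6A, a histone demethylase, averaged 43.7 against 58.6 scaled CPM (−0.41 ± 0.09, adjusted p = 0.015). That list was lower (7.42e-13 with the preset and adjusted p = 3.46e-09 with an estimated correlation, 4e-04 with the set term as well, 1.37e-07 within set 1 and 0.811 within set 2). TBL1X, part of a corepressor complex (54.1 against 40.9 scaled CPM, 0.48 ± 0.1, adjusted p = 0.0158), and ENTHD1 (0.24 ± 0.05, adjusted p = 0.0211) were higher in males. Within set 2, TBL1X (0.08), EIF2S3 (−0.4) and KDM6A (−0.4) did not pass in limma. Set 2 held both libraries whose sex genes went against the label, described below, and they were kept under their labels. Its sex results, the 0.811 of the list among them, therefore cannot decide whether these differences recur there. ENTHD1 did not pass within set 1 (0.165, adjusted p = 0.963) or set 2 (0.369, adjusted p = 0.411). With CPM as deposited, KDM6A (adjusted p = 0.1) and TBL1X (0.0501) did not pass, nor with RLE size factors (adjusted p = 0.0752 for both). The preset correlation called 8 further lists; with an estimated one, cell proliferation had adjusted p = 0.308 with an estimated correlation and the other 7 had adjusted p = 0.618 with an estimated correlation.

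In 2 libraries of set 2 the sex genes went against the label. The library labelled Control_Male_Weaned replicate 7 had 0.0233 scaled CPM of EIF1AY, and 17 of 20 sex genes lay nearer the female mean. The library labelled MIA_Female_Nursed replicate 6 had 86.3 scaled CPM, and 15 of 20 lay nearer the male mean. The other 36 male-labelled libraries had 34.4 to 85.1 scaled CPM of EIF1AY, and the other 35 female-labelled ones at most 0.026. Both were kept under their labels, and without them the counts were 56 genes for MIA (51 higher, 5 lower), 57 for weaning and 22 for sex.

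**Figure D4:**
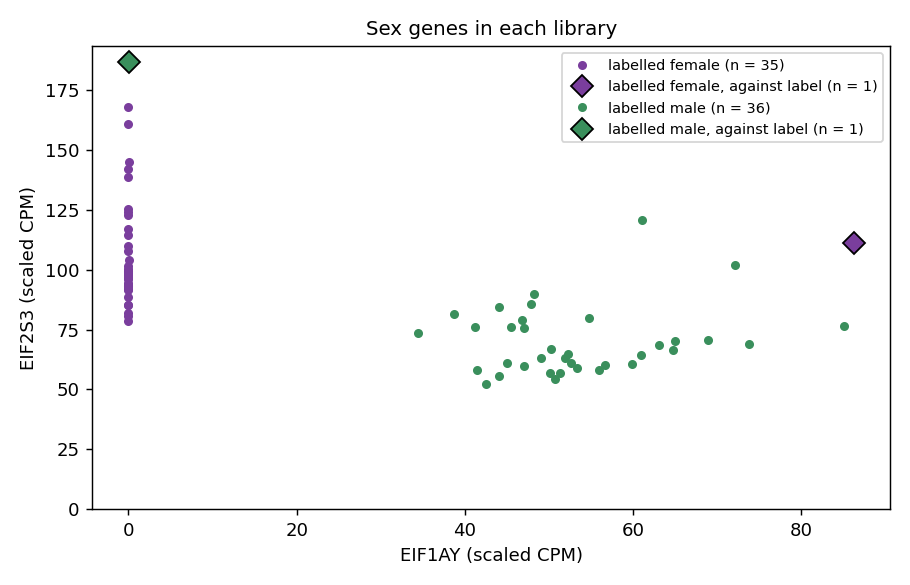
Each point is a library, with scaled CPM of the Y-linked gene EIF1AY on the x axis and of the X-linked gene EIF2S3 on the y axis, by labelled sex. Diamonds mark the 2 libraries at 0.0233 (labelled male) and 86.3 scaled CPM (labelled female) of EIF1AY.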

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

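The tests of the red cell genes and of the glucocorticoid-induced genes without the genes named for weaning were written before their results were seen. So were the interaction contrasts of the gene lists. The other tests given here, the splits of the samples among them, were chosen only after the result was seen.

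MIA pigs had higher levels of 50 genes, immune genes among them, by a median log2 fold change of 0.63 over all 50. The library set as the whole cause was argued against, since set and group were not associated (Fisher's exact test, p = 0.98) and 54 of 54 genes kept their call with the set term. Their same direction in both sets is no separate support, since the genes were picked over the same pigs. Blood left in the tissue was argued against too, since the mean difference of 7 red cell genes had an upper 95% limit of 0.301. A wider spread among MIA pigs was found: the antigen presentation score (27 genes) had an SD of 0.737 in MIA and 0.243 in control pigs within library sets, a variance ratio of 9.11 (permutation p = 1e-05, the smallest that 100000 resamples can give). Of the 33 MIA pigs, 17 lay above every control pig of their set and 6 below the control median of their set. A litter or an infection shared by some pigs could also give this pattern. Such a cause cannot be told apart from an effect of MIA because litter and sow are not given in the sources used here. The permutation p takes the pigs as independent. Seen afterwards, in set 1 the MIA pigs with replicate number 1 scored 2.636 to 3.275 and those with number 3 scored 3.962 to 5.083. Those with numbers 2, 4, 5 and 6 lay on both sides of the highest control pig of that set. The tissue moved with this score in set 1, where MIA pigs above every control pig had myelin scores of −0.918 to 0.395. The other MIA pigs of set 1 had 0.438 to 2.164, save MIA_Male_Nursed replicate 4 at −0.375, and in set 2 the ranges overlapped. With the set term and tissue scores 54 of 54 genes kept their call, but tissue as a cause of the spread was not tested. A lasting effect of MIA on immune cells of the hypothalamus in part of the offspring stays a candidate explanation, untested against litter.

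Weaned pigs had higher glucocorticoid-induced and lower proliferation genes. The library set as the whole cause was argued against, since 35 of 35 genes kept their call with the set term. Their same direction in both sets is no separate support, since the genes were picked over the same pigs. With scores of hypothalamic transcription factors and myelin genes as terms, 35 of 35 also kept their call. That argues against the tissue measured by these 2 scores as the whole cause. Other tissue taken at dissection was not tested. No score of ependymal and tanycyte markers was used, and that list was lower in weaned pigs with the preset correlation alone. The glucocorticoid-induced list without the genes named for weaning, 18 members, was still higher with the set term and an estimated correlation (adjusted p = 0.0236), which is consistent with a rise that is not limited to PDK4 and FKBP5. With CPM as deposited 29 of the 35 passed and 35 kept their direction, in another list of 35 genes (17 higher, 18 lower). Stress hormones at weaning are a candidate explanation that the design names no measure for, and fasting before sampling was not tested.

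In 2 libraries of set 2 the sex genes went against the label. RNA of another pig mixed in was argued against, since the library labelled female had 86.3 scaled CPM of EIF1AY, above all other male-labelled libraries, and the library labelled male had 0.0233. On 221 genes called for weaning without both libraries, where 0 is the mean of the nursed and 1 that of the weaned libraries of the set, MIA_Female_Nursed replicate 6 lay at 1.15 (the other 10 nursed libraries −0.371 to 0.403) and Control_Male_Weaned replicate 7 at 0.471 (the other 13 weaned ones 0.549 to 1.4). On 182 genes called for MIA without both, with 0 for control and 1 for MIA libraries, MIA_Female_Nursed replicate 6 lay at 0.789, within the other 9 MIA libraries (0.217 to 2) and above the other 14 control ones (−0.402 to 0.45), and Control_Male_Weaned replicate 7 lay above the control ones at 0.504. An exchange of the labels of these 2 libraries cannot be told apart from separate wrong labels. On the weaning genes MIA_Female_Nursed replicate 6 takes the place that an exchange needs. The genes and ranges came from the other libraries, which parts those more than libraries left out. The positions 0.471 and 0.504 of Control_Male_Weaned replicate 7, just outside a range, therefore decide nothing. On the MIA genes MIA_Female_Nursed replicate 6 keeps the place of its label. It had 14.7 scaled CPM of OAS1 against at most 8.84 in those control libraries and 36.9 of RSAD2 against 12.3. Its antigen presentation score of 2.346 lay below that of Control_Female_Nursed replicate 10 of the same set (2.384), so that score does not place it. No biological explanation was tested.

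Among 5 library measures in the 7 groups of 7 to 10 pigs, 2 of 35 combinations had a library that stood apart, where chance sets about 5% apart; Control_Female_Weaned, with 11 pigs, was not tested, and library sets were not told apart. Control_Female_Nursed replicate 8 had 70.95 M assigned reads, against 54.3 M in the next library of its group. MIA_Male_Nursed replicate 7 had a score of hypothalamic transcription factors of −0.994, against −0.048 in the next, and 217.8 scaled CPM of SETD7. Its score lies within the range of its own set 2 (−1.205 to 0.131, mean −0.522), and 6 of the 7 other libraries of its group are in set 1.

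Among named genes in the same 7 groups, 64 of 371 gene and group combinations had a pig that stood apart, over 53 genes. The 5% set apart by chance holds for 1 even group. Here the levels were not on the log2 scale and library sets were not told apart, so the excess over 5% cannot be read as pigs out of place. Levels are scaled CPM and high unless said otherwise. MIA_Male_Nursed replicate 6 was high in interferon genes, with OAS1 87.6, OAS2 227, IRF9 117, HERC6 192, DDX60 61, and RSAD2 164, and had MRO 12.9, TMEM100 134, FIBIN 107.5, BUB1B 18.9, MCM3 16.6 and RRM2 40.6. MIA_Male_Weaned replicate 2 was high in class II genes, with SLA-DRA 73.4, SLA-DQA1 43.3, SLA-DRB1 45.1 and SLA-DQB1 33.3, and had CD3D 1.22 and CYP4F55 30.7. Control_Male_Weaned replicate 8 had GNLY 1.06, SLA-DRA 12.2, CD3D 0.246, GZMA 0.387, DTL 2.85 and FKBP5 122, and was low in POLE (0.704) and MCM3 (2.36). MIA_Male_Weaned replicate 3 had TMEM100 168, IL17RB 12.03, FIBIN 168, TBATA 4.12, MCM3 9.45 and RRM2 10.5. MIA_Female_Nursed replicate 6 had RSAD2 36.9, PDK4 136, SETD7 252 and EIF1AY 86.3, and Control_Male_Weaned replicate 7 had EIF2S3 187 and was low in EIF1AY (0.0233). MIA_Female_Weaned replicate 7 had FPGT 15.9, EIF2S3 145 and KDM6A 109. Its EIF1AY stood apart at 0.0198 against 0 in the next library of its group, but lay below the floor of 0.22 scaled CPM. In other MIA pigs, MIA_Female_Weaned replicate 6 had GNLY 4.38, replicate 3 OAS2 106 and RSAD2 37.4, replicate 5 MRO 17.1 and replicate 1 ENTHD1 0.2101; MIA_Female_Nursed replicate 1 had OAS1 39.1 and replicate 7 GZMA 0.577 and a low SSPN (31.6); MIA_Male_Nursed replicate 2 had SLA-DRB1 36.5. Among nursed control pigs, Control_Female_Nursed replicate 2 had SELP 5.29 and CCL5 1.15, and replicate 7 SLA-DRB1 5.35 and TBATA 4.67. Control_Male_Nursed replicate 1 had SLA-DRA 2.82, replicate 3 SLA-3 62.7, replicate 4 CD3D 0.129, replicate 5 a low SSPN (36.97), replicate 6 FPGT 29.5, and replicate 8 HAO2 4.45 and CD3E 0.221. Control_Male_Weaned replicate 9 was low in FPGT (11.9).

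Differences between groups in an effect were called for gene lists, by the interaction contrasts with the preset correlation, in 11 lists for MIA by weaning, 7 for MIA by sex and 18 for weaning by sex, and in 0 lists each with an estimated correlation.

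The same pigs were split 100 times into 8 groups of the same sizes, the real split included. As many genes as the real 54 for MIA came in 1 split (highest other 1). As many as the 35 for weaning came in 3 (highest other 10936), and as many as the 20 for sex in 1 (highest other 0). These splits cross the library sets. No splits here or below keep litters together, since litter and sow are not given, so chance is judged for pigs taken as independent. On that footing the share of splits was under 0.05 for each of these counts, which argues against chance. The shares were not adjusted over the counts judged. For weaning chance is not excluded, since another split called 10936 genes. The share was also under 0.05 for the 1 gene for MIA in weaned pigs (2 splits, highest other 9838), but these splits cross the library sets. That count was 0 in the weaned pigs alone and without the 2 libraries whose sex genes went against the label, so little rests on it. For the 9 genes for weaning in control pigs the share was under 0.05 (4 splits), but chance is not excluded (highest other 10584). For the 1 gene for weaning in MIA pigs the share argues against chance (1 split, highest other 0). For the counts of 0 all 100 splits gave as many: the highest other was 0 for MIA by weaning, 13395 for MIA by sex, 12660 for weaning by sex, 0 for the interaction of all 3 factors and 7825 for MIA in nursed pigs. Splits that call so many genes point to a structure of the samples. With the set term the shares argue against chance for 185 genes for MIA (1 split, highest other 0), 171 for weaning (1, highest other 1) and 27 for sex (1, highest other 1). The same holds for 34 for MIA in weaned pigs (1, highest other 1). The share was also under 0.05 for 110 for weaning in control pigs (4, highest other 3827) and 19 for weaning in MIA pigs (2, highest other 25). For these 2 counts another split called more genes, so chance is not excluded. The counts of 0 in that fit came in all 100 splits, with a highest other of 1935 for MIA by weaning, 690 for MIA by sex, 0 for weaning by sex, 16 for all 3 factors and 0 for MIA in nursed pigs, so a structure of the samples remains within the library sets.

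For gene lists with the preset correlation, chance cannot be excluded: 18 of 100 splits gave as many as the 15 for MIA (highest other 24), 57 as the 10 for weaning (highest other 22) and 62 as the 9 for sex (highest other 19). For interactions it was 43 splits for the 11 of MIA by weaning (highest other 19), 83 for the 7 of MIA by sex (highest other 21) and 6 for the 18 of weaning by sex (highest other 20). With an estimated correlation, 3 splits gave as many as the 3 lists for MIA (highest other 3) and 2 as the 2 for weaning (highest other 4), shares under 0.05. For the 1 list for sex it was 13 splits (highest other 2), so the count alone does not exclude chance. The count takes no account of how far that list, the X-linked genes, passed (camera, adjusted p = 3.46e-09 with an estimated correlation). With the set term as well, the splits were 1 for the 2 lists of MIA (highest other 1), 3 for the 2 of weaning (highest other 2) and 4 for the 1 of sex (highest other 1). Each share was under 0.05, without adjustment over the counts judged.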

How the results depend on the processing

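The fits with the set term, its scores, library sets, libraries left out, pseudocounts and CPM as deposited were chosen only after the data were seen. Of 1725 comparisons of a named gene's result under an alternative with its result as reported, 1540 stayed on the same side of the threshold with the same direction, 105 passed no longer, 5 passed newly and 75 turned direction; 60 of the 105 came with set 2 alone, 20 with set 1 alone, where fewer libraries were tested, and 11 with CPM as deposited. The 5 came with sample weights, where RYR1 passed for MIA by sex (adjusted p = 0.00919), TRH for MIA (0.0222), CRH for weaning (0.041), and FAM72A (0.0221) and CCDC17 (0.0105) for MIA in nursed pigs. The pseudocount weighs on genes at low levels such as GNLY and CCR2. Their log2 fold changes for MIA went from 1.68 and 1.08 at a pseudocount of 0.1 CPM to 0.47 and 0.18 at 2 CPM, and passed with each. The planned DESeq2 Wald test and surrogate variables from svaseq were not run, since both need counts, and sample weights were estimated by limma without voom. Additive models and models without the interaction of all 3 factors kept every count within 1.5 times. Where a cause is not given below, the cause was not tested.

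Counts of genes are given for MIA, weaning, MIA in weaned pigs, weaning in control pigs and weaning in MIA pigs, which were 54, 35, 1, 9 and 1 as reported. The set term gave 185, 171, 34, 110 and 19, by removing the spread between sets. The set term and tissue scores gave 476, 745, 93, 388 and 57. The set term without the 2 libraries that deviated most from that fit (Control_Male_Weaned replicate 8 and MIA_Female_Nursed replicate 1, root mean square 0.795 and 0.659 on the log2 scale, against 0.537 in the next) gave 235, 238, 32, 81 and 13, and without the 2 whose sex genes went against the label 182, 221, 37, 135 and 24. Set 1 alone gave 94, 152, 0, 26 and 23, and set 2 alone, with 25 libraries, 1, 0, 0, 0 and 0. Sample weights gave 1515, 611, 643, 260 and 83, with 37 for sex, 3 for MIA by sex and 110 for MIA in nursed pigs against 20, 0 and 0. Without the 2 libraries whose sex genes went against the label, weaning had 57 and MIA in weaned pigs 0. For MIA in weaned pigs a pseudocount of 0.1 CPM gave 10 and the weaned pigs alone 0. For weaning in MIA pigs, RLE size factors, no filter and CPM as deposited each gave 2, and CPM as deposited gave 3 for weaning in control pigs.

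The replicate block, the replicate number of the labels as a term, gave 65 genes for MIA (56 higher, 9 lower; 43 of the 54 among them, and 54 in the same direction), 52 for weaning (29 higher, 23 lower) and 20 for sex. It gave 6 for MIA in weaned pigs and 4 for weaning in MIA pigs, 8 lists for MIA and 3 for MIA by sex, and changed no other count by over 1.5 times. Among the genes not called for MIA with the block were RSAD2 (adjusted p = 0.0555), DDX60 (0.0508) and HAO2 (0.0699). The replicate block with the set term gave 397, 235, 80, 100 and 17 in the order above, against 185 for MIA with the set term alone. The numbers were not taken as pairs: of 233 pairs of libraries with the same number in different groups, 185 had a correlation of deviations over 0.1 (median 0.711, lowest −0.921, and a median of 0.327 for different numbers), and 12 of 73 libraries matched best with their own number. After the set term it was 117 pairs (median 0.1, against −0.0098 for different numbers) and 19 libraries, so a litter, batch or day shared by number is not excluded.

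Counts of lists for MIA, weaning, sex, MIA by weaning, MIA by sex and weaning by sex were 15, 10, 9, 11, 7 and 18 as reported. An estimated correlation gave 3, 2, 1, 0, 0 and 0, and so did fry, without and with the set term. An estimated correlation with the set term gave 2, 2, 1, 0, 0 and 0, the same numbers without the 2 libraries whose sex genes went against the label, 1, 2, 1, 0, 0 and 0 in set 1, and 0 for all 6 in set 2. With the preset correlation the set term gave 5 for sex and 6 for MIA by weaning, also without the 2 libraries that deviated most. The set term and scores gave 4 for sex, 4 for MIA by sex and 6 for weaning by sex, no filter gave 5 for sex, and leaving out the 2 libraries whose sex genes went against the label 5 for MIA by weaning.

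Leaving out 1 library at a time gave 36 to 85 genes for MIA (85 without MIA_Male_Nursed replicate 1), 28 to 50 for weaning, 20 to 22 for sex, 6 to 11 for weaning in control pigs, 1 to 2 for weaning in MIA pigs, 0 to 10 for MIA in weaned pigs, and 0 for the interactions and for MIA in nursed pigs. The 1 gene for MIA in weaned pigs, GIMAP7, is decided by single libraries: the count was 0 without any 1 of Control_Female_Nursed replicates 3, 6, 8, Control_Female_Weaned 3, 4, 6, 10, 11, Control_Male_Nursed 2, 5, 9, Control_Male_Weaned 3, 4, 5, 6, 7, 9, MIA_Female_Nursed 2, 4, MIA_Female_Weaned 1, 2, 3, 4, 6, MIA_Male_Nursed 1, 5 and MIA_Male_Weaned 2, 3, 4, 5, 10. It was 2 without MIA_Male_Nursed replicate 4, 4 without MIA_Male_Weaned 6, 6 without Control_Male_Weaned 8 or MIA_Male_Weaned 1, 7 without MIA_Male_Nursed 2, 8 without MIA_Female_Weaned 5 or MIA_Male_Weaned 9, 9 without MIA_Female_Weaned 7 and 10 without MIA_Male_Weaned 8. For weaning in MIA pigs it was 2 without Control_Female_Nursed replicate 10, Control_Male_Nursed 3, 8, 10, Control_Male_Weaned 4, 7, MIA_Female_Nursed 1, 5, MIA_Female_Weaned 7, MIA_Male_Nursed 5, 6 or MIA_Male_Weaned 2, 8, 9. In fits with the set term the ranges were 143 to 249 for MIA, 147 to 221 for weaning and 23 to 29 for sex. They were wider within strata, where 20, 10 and 12 libraries moved the count by over 1.5 times: 1 (without MIA_Female_Weaned replicate 6) to 70 (without MIA_Male_Nursed replicate 6) for MIA in weaned pigs, 47 (without Control_Male_Nursed replicate 9) to 226 (without Control_Male_Nursed replicate 6) for weaning in control pigs, and 6 (without MIA_Female_Nursed replicate 5) to 28 (without MIA_Male_Nursed replicate 8) for weaning in MIA pigs.

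The 75 results that turned direction were all of neuropeptide genes that passed neither as reported nor in the alternative. Their log2 fold changes as reported were, for MIA, AGRP 0.41, NPY 0.227, POMC 0.295, CARTPT 0.364, HCRT 0.511, CRH 0.042, AVP 0.98, OXT 0.268, TRH −0.009, GHRH 0.31, SST 0.029, KISS1 0.352, GAL 0.49 and PDYN 0.412, and for weaning, AGRP −0.325, NPY −0.22, POMC −0.533, CARTPT −0.01, HCRT 0.134, AVP −0.355, OXT −0.376, TRH −0.408, GHRH −0.212, KISS1 −0.441, GAL −0.428 and PDYN −0.176. The set term gave CRH −0.037, OXT −0.069 and SST −0.079 for MIA, and CARTPT 0.076 for weaning. The set term and tissue scores gave POMC −0.061, HCRT −0.265, CRH −0.092, OXT −0.29, SST −0.187, GAL −0.001 and PDYN −0.159 for MIA, and AGRP 0.001, NPY 0.072, CARTPT 0.194, AVP 0.366, OXT 0.364, TRH 0.02, GHRH 0.026, GAL 0.016 and PDYN 0.124 for weaning. The set term without the 2 libraries that deviated most gave CRH −0.017 and SST −0.014 for MIA. The set term without the 2 libraries whose sex genes went against the label gave CRH −0.011, OXT −0.059 and SST −0.072 for MIA. Those 2 left out and no set term gave TRH 0.056 for MIA. The replicate block gave NPY −0.04, POMC −0.187, HCRT −0.228, CRH −0.094, OXT −0.456, SST −0.201 and GAL −0.055 for MIA, and CARTPT 0.137 and PDYN 0.02 for weaning. The replicate block and the set term gave CRH −0.038, OXT −0.222 and SST −0.131 for MIA, and CARTPT 0.135 and PDYN 0.015 for weaning. Sample weights gave CARTPT −0.115, HCRT −0.17, CRH −0.356, AVP −0.287, OXT −1.206 and SST −0.156 for MIA, and CARTPT 0.064, AVP 0.539 and OXT 0.12 for weaning. Set 1 alone gave CARTPT −0.187, HCRT −0.343, CRH −0.112, OXT −0.71, SST −0.11 and PDYN −0.074 for MIA, and CARTPT 0.155, AVP 0.38, OXT 0.238 and PDYN 0.115 for weaning. Set 2 alone gave AGRP −0.445, NPY −0.689, POMC −0.753, TRH 1.044, GHRH −0.18 and KISS1 −0.407 for MIA, and AGRP 0.129, NPY 0.034, POMC 0.241, HCRT −0.066, GHRH 0.205 and KISS1 0.118 for weaning. A pseudocount of 0.1 CPM gave TRH 0.082 for MIA, and CARTPT 0.029 for weaning. CPM as deposited gave TRH 0.003 for MIA. The additive model gave HCRT −0.033 for weaning.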

Other observations

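The genes in this paragraph, and the correlations in the next, were chosen only after their values were seen. Among genes that rose in weaned pigs with the set term were SDS, an enzyme that deaminates serine (log2 fold change 0.81 ± 0.1, adjusted p = 2.26e-07, against 0.74 ± 0.19 and 0.067 without the set term), and CBS, which converts homocysteine (0.61 ± 0.09, adjusted p = 1.71e-05, against 0.53 ± 0.2 and 0.921). FAM107A, a gene that glucocorticoids induce in the brain, rose in both fits (114 ± 28.8 against 81.6 ± 26.7 scaled CPM, 0.5 ± 0.1, adjusted p = 0.00905). FOXO3, a transcription factor that insulin signalling restrains, rose as well (0.16 ± 0.04, adjusted p = 0.025). Among genes that fell with the set term were MCM2, a helicase subunit (−0.5 ± 0.07, adjusted p = 8.37e-07, against −0.57 ± 0.19 and 0.483), the cell cycle regulator E2F1 (−0.45 ± 0.08, adjusted p = 0.000362, against −0.53 ± 0.21 and 0.946), HES5, a target of Notch signalling in neural precursors (−0.66 ± 0.12, adjusted p = 0.000805, against −0.79 ± 0.32 and 0.946), and the clock output gene DBP (−0.36 ± 0.07, adjusted p = 0.00125, against −0.47 ± 0.27 and 0.946). In MIA pigs, TBX21, a transcription factor of killer and helper lymphocytes (0.46 ± 0.1, adjusted p = 0.0094), LCK, a kinase of T cells (0.59 ± 0.13, adjusted p = 0.0214), and SIGLEC1, a receptor of macrophages that interferon induces (0.7 ± 0.16, adjusted p = 0.0214), rose in both fits. B2M, the light chain of class I molecules, rose with the set term (0.64 ± 0.15, adjusted p = 0.0184, against 0.73 ± 0.2 and 0.13).

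Scores of immune genes moved together within MIA pigs. Each score was the mean log2 level of 10 class II genes, 5 lymphocyte genes or 37 interferon genes, and 8 relations were computed, each within 1 library set and within MIA or control pigs. In MIA pigs of set 1 (n = 23), the lymphocyte and class II scores had r = 0.964 and rho = 0.943 (permutation p = 1e-05 for both, the smallest 100000 resamples can give, adjusted 4e-05), and r = 0.952 without the 2 pigs farthest from the median. In MIA pigs of set 2 (n = 10) they had r = 0.805 (permutation p = 0.0076, adjusted 0.02) and rho = 0.867 (p = 0.0023, adjusted 0.0061), and r = 0.847 without the 2 farthest. In control pigs r was 0.0716 and rho 0.00462 in set 1 (n = 25, permutation p = 0.74 and 0.98), and 0.285 and 0.104 in set 2 (n = 15, permutation p = 0.3 and 0.71). Without the 2 farthest, r was 0.0534 and −0.117. Over all control pigs the medians of the lymphocyte genes CD3D, CD3E and GZMA were 0, 0.0434 and 0.0219 scaled CPM. These genes had little room to vary there, so the lack of a relation in control pigs does not show that it is particular to MIA pigs. The interferon and class II scores had r = 0.782 and rho = 0.867 in MIA pigs of set 1 (permutation p = 1e-05, adjusted 4e-05; r = 0.912 without the 2 farthest), and r = 0.613 and rho = 0.624 in MIA pigs of set 2 (permutation p = 0.064 and 0.061, adjusted 0.13 and 0.12). For the latter r was 0.352 without the 2 farthest pigs, so that it rests on them. In control pigs they had r = 0.318 and rho = 0.199 in set 1 (permutation p = 0.12 and 0.34), and −0.0338 and −0.129 in set 2 (permutation p = 0.9 and 0.65). Without the 2 farthest control pigs r was 0.449 in set 1 and 0.0899 in set 2.

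The 2 library sets differed in markers of regions and cells as well as in processing traits. The score of hypothalamic transcription factors averaged 0.272 in set 1 and −0.522 in set 2, and that of myelin genes 0.326 and −0.626. Of the 17638 genes that differed between the sets, 8748 were higher and 8890 lower in set 2. No 2 libraries were identical; the highest correlation between libraries was 0.996, and the median was 0.985 within and 0.856 between sets.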
